A study of Mus musculus with 9 samples.

How the data were processed

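Total RNA from 9 mouse hearts (5 WT, 4 RORasg/sg) was hybridised to single-colour Agilent arrays. Per the labels' protocols, whole-transcriptome amplification (NuGEN Ovation Pico WTA) started from 70 ng of total RNA, and 5 ug of its product was labelled with Cy3 (Agilent SureTag). Mice had been weaned at 3 weeks and fed NIH31 diet. Per the file headers, the arrays (design 014868, grid build mm9) were read with Feature Extraction 12.0.0.7 under protocol GE1_1200_Jun14, and the submitters' processing notes name Agilent Feature Extraction 12. The deposited intensity of each spot, as processed by Feature Extraction, is background-subtracted, linear and not scaled between arrays. The deposited value table of the series held the same processed intensity: the largest relative difference over 45018 features was 0 on each array, so its scale, centring and direction are those of the scanner files. Its column medians were 139, 118, 110, 80.2, 90.7, 126, 55.4, 81.1 and 55.2 for WT 1 to 5 and RORasg/sg 1 to 4.

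Of 45018 spots, 43379 were not controls. Spots with an outlier flag were left out (758 over the 9 arrays), none was saturated, and spots of one probe were averaged. Values are log2 of the processed signal minus each array's 75th percentile. Probes well above background on at least 4 of the 9 arrays were kept (36404 of 41174), and each gene was represented by the kept probe with the highest mean over the arrays, which left 27774 genes. Probes were named through their accession in a table of assembly GRCm38.p6, which matched 28223 of 41174 probes and 19096 symbols. Others keep the accession as their name. That assembly differs from the grid build, so it was used for names and neighbours, and no coordinates are given.

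The groups were compared with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tables were read with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15. The 29 gene lists were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. For Rora and AI593442 an exact permutation test was also run. The overlap of calls between 2 settings was set against RORasg/sg hearts simulated gene by gene from a normal distribution with the WT mean and SD. The hearts came from separate mice, and the number of arrays limits the precision.

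The text names every probe of Rora, the genes passing the threshold (the 8 with the smallest p in a direction where fewer than 5 passed), and up to 4 members of each list with the smallest p. Some members that this rule names are not reported here. This rule, the lists, the tests and most alternatives were set before the data were examined. The alternatives were other normalizations, normexp background correction (offset 50, on the median spot signal, since the files hold no mean signal), other filters and probe rules, slide and replicate number as blocks, array weights, other eBayes settings, and leaving out each array. The 5 brighter arrays, the 4 dimmer arrays and brightness as a covariate were added after the data were examined. Slide 1 held WT 1 and 2 and RORasg/sg 1 and 2, slide 2 held WT 3 and 4 and RORasg/sg 3 and 4, and slide 3 held WT 5. The highest correlation between 2 arrays was 0.979. Genes within 20 Mb of Rora were compared with the others by Fisher's exact test, and counts were repeated over 100 of the 126 splits of the arrays into 5 and 4.

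The pipeline was tested on simulated data for the comparison of 5 WT with 4 RORasg/sg arrays, with 40 genes changed at each fold size among 27686 genes. It recovered 0% of genes changed 2-fold, 17.5% at 4-fold, 70.0% at 8-fold, 70.0% at 16-fold and 97.5% at 64-fold, with 7 false calls. The list with a simulated shift was called and 0 of 28 unshifted lists were. The simulated genes were drawn independently of each other. The list calls thus do not show how often camera calls an unshifted list when genes vary together.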

Results

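Gene expression was measured in the hearts of male mice labelled C57BL/6, aged 3 to 4 months and given no treatment. The 9 hearts came from 5 wild-type (WT) mice and 4 mice homozygous for the staggerer mutation (RORasg/sg), a deletion inside Rora, the gene of the nuclear receptor RORalpha. Each heart was hybridised to 1 single-colour Agilent array. The comparison asked which heart transcripts differ when RORalpha is lost, in a study of RORalpha and cardiac hypertrophy.

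The arrays differed in brightness. The 75th percentile of processed signal was 684, 643, 631, 436 and 547 in WT hearts 1 to 5, and 773, 292, 391 and 264 in RORasg/sg hearts 1 to 4. Between 80.7% and 87.8% of probes were well above background on each array. Across genes, the median correlation with the brighter WT arrays was 0.961 for RORasg/sg 1, 0.894 for WT 4, and 0.861, 0.809 and 0.756 for RORasg/sg 2, 3 and 4. WT 4 and RORasg/sg 2, 3 and 4 are called the 4 dimmer arrays (75th percentile under 500), and the other 5 the brighter arrays. The brighter arrays hold 4 WT hearts and a single RORasg/sg heart, so values from them have no replicate in the RORasg/sg group, and WT 4 is the single WT heart of the dimmer arrays. Tests within either set assume that the lone heart varies like the hearts of the other group. The median log2 difference of all genes was -0.34 in the 5 brighter and 0.50 in the 4 dimmer arrays, and list medians from those arrays are to be read against these. This division was chosen after the data were examined.

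**Figure D1:**
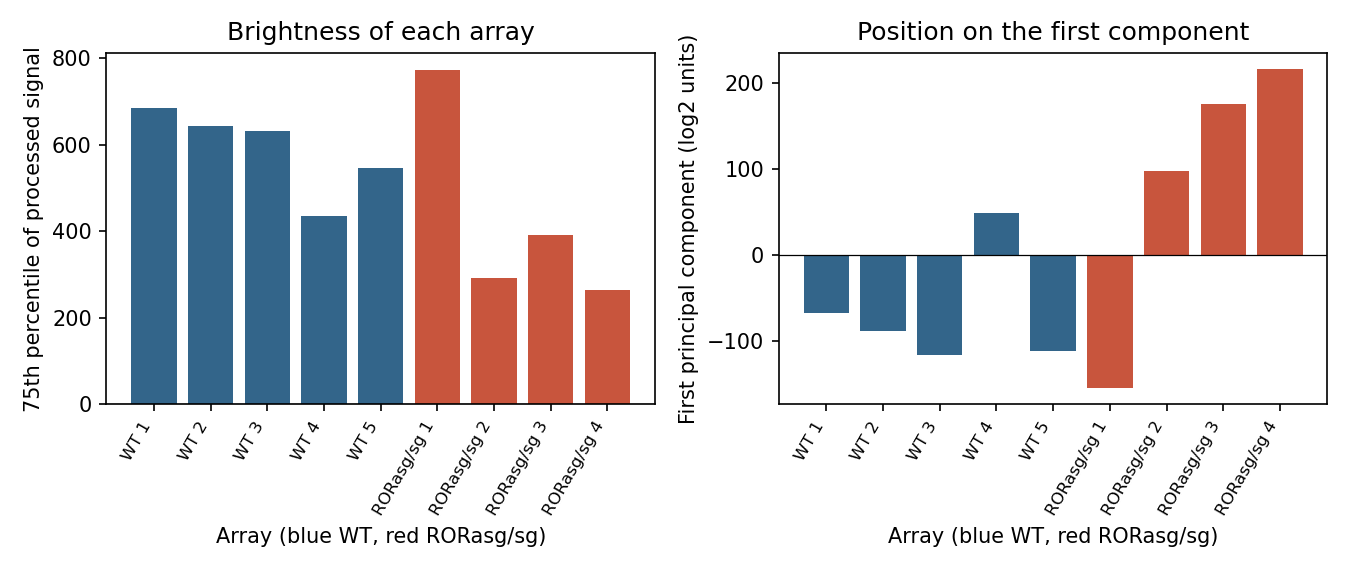
Bars give, for each array, the 75th percentile of processed signal (left, linear units) and the position on the first principal component of log2 signal (right), with WT in blue and RORasg/sg in red. WT 4 stands at 49.3 on the component, on the side of RORasg/sg 2, 3 and 4, while RORasg/sg 1 stands at -155 beside the other WT arrays.

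Rora, the mutated gene, was lower in all 4 RORasg/sg hearts than in any WT heart. Its probe A_51_P477779 read 2.72 ± 0.699 in WT hearts (SD, n = 5) and -1.41 ± 1.21 in RORasg/sg hearts (SD, n = 4), in log2 units around each array's 75th percentile, or 17.5-fold less in RORasg/sg. The WT hearts 1 to 5 read 2.87, 3.29, 2.88, 1.51 and 3.06, and the RORasg/sg hearts 1 to 4 read 0.083, -2.71, -1.01 and -1.99. An exact two-sided permutation test gave p = 0.0159, the smallest that 126 splits allow. In limma, the log2 difference of -4.13 (SE 0.610) had an adjusted p of 0.224 over 27774 genes and so did not pass the threshold. A second bright probe, A_52_P652442, differed by -5.34 (SE 0.816), again lower in every RORasg/sg heart than in every WT heart, and the dim probe A_52_P652950 by -1.08 (SE 0.768), with overlapping groups. Leaving out RORasg/sg 1 brought Rora past the threshold (-4.63, adjusted p = 0.00137), and it was -2.94 (adjusted p = 0.00170) in the 5 brighter arrays, which rests on 1 RORasg/sg heart. Over 29 alternatives the adjusted p ran from 1.36e-04 to 0.9998, and within slides 1 and 2 the log2 difference was -4.40 and -3.70. The position of each probe against the deleted part is not known, and a probe outside it does not check the genotype labels.

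AI593442 was the gene that passed the threshold genome-wide, and it fell by 4.74 on the log2 scale (SE 0.502, limma adjusted p = 0.0180). It read 0.26 ± 0.453 in WT and -4.48 ± 0.926 in RORasg/sg hearts (SD, n = 5 and n = 4), 26.7-fold less, with this probe well above background in 3 of the 4 RORasg/sg hearts. Each of its 3 probes was lower in every RORasg/sg heart than in every WT heart. The other probes differed less, by -2.77 and -2.68. The call was lost with probes well above background on all arrays (-2.77, adjusted p = 0.240) and with the mean of its probes (-3.40, adjusted p = 0.119). The gene lies on chromosome 9, as Rora does, within 20 Mb of it in the GRCm38.p6 annotation. Its adjusted p lay between 0.00121 and 0.121 when single arrays were left out. The call was also lost without WT 1 (0.0947), WT 2 (0.121), WT 3 (0.0556), WT 4 (0.0842), WT 5 (0.111), RORasg/sg 2 (0.0921) or RORasg/sg 3 (0.0941). An exact two-sided permutation test gave p = 0.0159, again the smallest possible. Any gene whose groups do not overlap gets that value, and AI593442 was picked for its small p, so the test adds no support. The adjusted p of AI593442 lay between 1.65e-04 and 0.9998 over 29 alternatives. It was 0.0447 with brightness as a covariate, and in the 5 brighter arrays the log2 difference was -5.05. With slide as a block the log2 difference was -4.62 (adjusted p = 0.141), and within slides 1 and 2 it was -4.96 and -4.28.

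**Figure D2:**
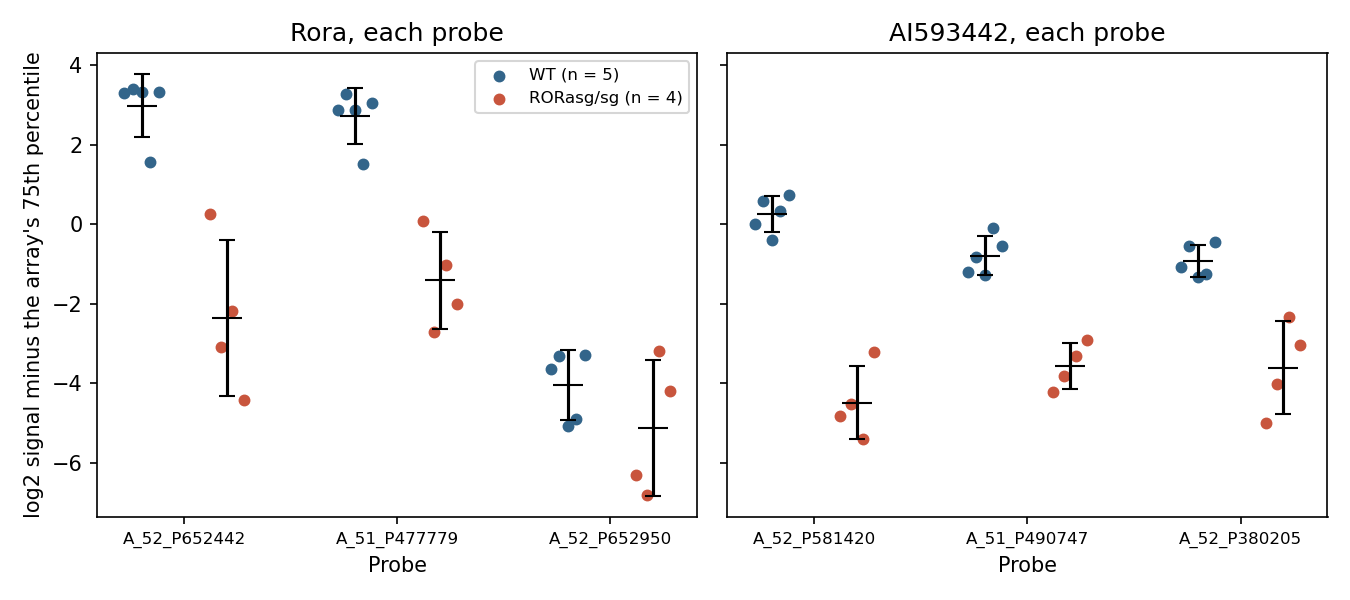
Points are single arrays (blue WT, n = 5; red RORasg/sg, n = 4) for each probe of Rora and AI593442, in log2 signal minus the array's 75th percentile; bars give the mean ± SD. All 3 AI593442 probes and Rora probes A_52_P652442 and A_51_P477779 show no overlap between the groups.

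Genome-wide, limma called 1 gene lower and 0 higher among 27774, while 3210 genes had an unadjusted p under 0.05. The median log2 difference of all genes was 0.41 with the 75th percentile scaling, 0.34 with each array's median, 0.30 with quantile normalization and -0.17 in the unscaled deposited values, and single-gene values are to be read against that shift. The count changed with single arrays. Without RORasg/sg 1 it was 10390 genes (7922 higher, 2468 lower), and without any one of the WT arrays, RORasg/sg 2 or RORasg/sg 3 it was 0. In the 5 brighter arrays it was 1189 (358 higher, 831 lower), with 1 RORasg/sg heart. These 2 sets of calls share 442 genes, 80 of them in the same direction and 362 in opposite directions, where the product of the counts per direction gives 176 and 269. Both use WT 1, 2, 3 and 5. With RORasg/sg hearts simulated without effect, at the spread of the 5 WT hearts with the dimmer WT 4 among them, the fit on the brighter arrays called 1442 genes on average and the fit without RORasg/sg 1 called 0, with 0 shared. Another simulation drew the lone heart at the spread of the 4 brighter WT arrays, which is the spread limma assumes for it. Few false calls were bound to follow, so that simulation is no check on the assumption. The number called without effect thus depends on the spread assumed for the lone heart. With the WT arrays split between the 2 fits (WT 1 and 2 with RORasg/sg 1, the others with RORasg/sg 2, 3 and 4), 3686 and 233 genes were called, 14 in the same and 30 in opposite directions. The overlap was examined, and the simulation made, after the counts were seen. Its genes were drawn independently, without the deviation that the dimmer arrays share, so its 0 calls are no yardstick for the 10390 genes. With 0 calls in that fit, the simulated shared count could only be 0.

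The other genes with the smallest p on the lower side did not pass the threshold. Mmp3, a matrix metalloproteinase, differed by -2.66 (SE 0.402, limma adjusted p = 0.224) and was lower in every RORasg/sg heart than in every WT heart. Slc22a3, an organic cation transporter, differed by -3.38 (SE 0.564), Cgref1 by -3.14 (SE 0.566), Mblac2 by -5.25 (SE 0.955) and AK033187 by -2.83 (SE 0.501, well above background in 3 of 4 RORasg/sg hearts). BC048679 was not well above background in any RORasg/sg heart, which gave at least 6.00-fold less there (limma adjusted p = 0.293). That bound sets the WT mean against the mean, per array, of the higher of the lowest signal well above background and the probe's own. Slc22a3 and Mblac2 were well above background in 1 of the 4 RORasg/sg hearts. The second probe of Mblac2 differed by 1.24, in the opposite direction, and was well above background in 2 of the 5 WT hearts.

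On the higher side, 0 genes passed in limma. Dtl, a substrate receptor of a cullin ubiquitin ligase that acts in S phase, differed by 2.42 (SE 0.405, limma adjusted p = 0.293). Its other probe, not well above background on any array, gave 0.38. Racgap1, a regulator of cytokinesis, differed by 2.49 (SE 0.530). Col6a3, a collagen VI chain, differed by 2.82 (SE 0.508) on the probe used and by 0.18 and 0.76 on its other probes. The probe at 0.76 was well above background in 1 WT heart and 0 RORasg/sg hearts. Serpinf1, a secreted serpin, differed by 1.59 (SE 0.335) and by 0.17 on its other probe. Prnd, a prion-like protein gene, differed by 1.82 (SE 0.383), 2210407C18Rik by 2.19, Ahdc1 by 2.16 and AB026047 by 1.76. In each of these genes, every RORasg/sg heart lay above every WT heart, and Ahdc1 was well above background in 2 of the 5 WT hearts.

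Of 29 gene lists fixed before the data were examined, 7 were called by limma's camera test with a preset correlation of 0.01, 6 downward and 1 upward against the other genes. None was called with an estimated correlation (lowest adjusted p = 0.321) or by fry (lowest adjusted p = 0.0727). Of their members, 0 passed the threshold over all genes in limma. List medians are to be read against the median of all genes, and the direction of a list is that against the other genes. The member values below are log2 differences, RORasg/sg minus WT, that did not pass over all genes. A value from the 5 brighter arrays, which hold 1 RORasg/sg heart, is given beside a member where its sign turned there. Members without one did not all hold there. Atf4 (-0.0069), Pln (-0.050), Tpi1 (-0.045) and Ifit3 (0.043) lay near 0 in those arrays, while Myh7 (-2.49) and Ccl7 (-1.58) did not.

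The sarcomere list of adult cardiomyocyte genes shifted downward (median -0.999, camera adjusted p = 6.72e-06, and adjusted p = 0.321 with an estimated correlation), and 3 of its 20 measured members had higher and 17 lower mean signal in RORasg/sg hearts. Pln, the inhibitor of the sarcoplasmic calcium pump, differed by -1.46 (SE 0.471), Myl2, the ventricular myosin light chain, by -1.29 (SE 0.440), Myom1 by -2.39 (SE 0.832) and Tcap by -1.06 (SE 0.322), which had no value in RORasg/sg 1 and 2 and rests on RORasg/sg 3 and 4. By limma, 0 members passed when adjusted over the list alone, with 0 higher and 8 lower at an unadjusted p under 0.05. The list's median deviation from the brighter WT arrays was -1.36 and -1.22 in RORasg/sg 3 and 4, but -0.051 and -0.15 in RORasg/sg 1 and 2. Within slide 1, camera's direction turned upward (median 0.099, adjusted p = 0.845), as in the 5 brighter arrays (adjusted p = 0.235), while within slide 2 it stayed downward (median -1.44, adjusted p = 8.40e-09). Over 31 alternatives its adjusted p ran from 8.39e-11 to 0.845, with 3.58e-04 under brightness as a covariate, and the call held when any single array was left out.

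Cell cycle genes shifted upward (median 0.74, camera adjusted p = 0.0376, and adjusted p = 0.321 with an estimated correlation), and 22 of its 25 measured members had higher and 3 lower mean signal in RORasg/sg hearts. Ccna2, the S and G2 phase cyclin, differed by 2.21 (SE 0.715), Kif11, a mitotic kinesin, by 1.64 (SE 0.562) and Mcm3, part of the replicative helicase, by 1.35 (SE 0.510), whereas Ccnd2 differed by -2.98 (SE 1.09, and 0.88 in the 5 brighter arrays, well above background in 3 of 4 RORasg/sg hearts). By limma, 0 members passed adjusted over the list alone, with 8 higher and 1 lower at an unadjusted p under 0.05. The list's median deviation was 1.26, 0.72, 0.99 and 0.42 in RORasg/sg hearts 1 to 4, against at most 0.36 in a WT heart. These deviations are not set against the shift of all genes in each array. Without RORasg/sg 1 the list's median was 0.684 and that of all genes 0.678. In RORasg/sg 2, 3 and 4 together the list thus moved about as all genes did. Within slides 1 and 2 the list's median was 0.81 (adjusted p = 9.45e-07) and 0.68 (adjusted p = 0.840). The call was lost without WT 4 (0.0654) or RORasg/sg 1 (0.689). Over the 5 brighter arrays its median was 1.26 (adjusted p = 7.54e-14, upward), which rests on 1 RORasg/sg heart. Over the 4 dimmer arrays it was 0.28 (adjusted p = 0.855), below the median of all genes there. Its adjusted p lay between 7.54e-14 and 0.855 over 31 alternatives, with 6.33e-10 under brightness as a covariate.

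The hypertrophy and fetal gene list shifted downward against the other genes (median -0.13, camera adjusted p = 0.0420, and adjusted p = 0.321 with an estimated correlation), and 10 of its 24 measured members had higher and 14 lower mean signal in RORasg/sg hearts. By limma, 4 members passed adjusted over the list alone, and 0 over all genes, with 1 higher and 6 lower at an unadjusted p under 0.05. Nppb, the gene of B-type natriuretic peptide, differed by -1.46 (SE 0.419), Myh7, the fetal myosin heavy chain, by -1.67 (SE 0.525), Ankrd1 by -1.76 (SE 0.496) and Acta1, skeletal actin, by -2.59 (SE 0.735). In the 5 brighter arrays the list's median was -0.27 (camera adjusted p = 0.971). Within slides 1 and 2 the median was 0.022 (adjusted p = 0.810) and -0.21 (adjusted p = 0.0112). The call was lost without WT 4 (0.110), WT 5 (0.0542), RORasg/sg 1 (0.0851), RORasg/sg 3 (0.0910) or RORasg/sg 4 (0.0599). Over 31 alternatives its adjusted p ran from 0.00262 to 0.971, with 0.0250 under brightness as a covariate.

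Renin-angiotensin and natriuretic signalling genes also shifted downward (median -0.073, camera adjusted p = 0.0376, and adjusted p = 0.321 with an estimated correlation), and 11 of its 23 measured members had higher and 12 lower mean signal in RORasg/sg hearts. By limma, 3 members passed adjusted over the list alone, and 0 over all genes, with 0 higher and 5 lower at an unadjusted p under 0.05. The 3 were Nppb (-1.46), Adra1a and Nr3c2, and Nppa was not among them. Nppa, the gene of atrial natriuretic peptide, differed by -1.20 (SE 0.434), Adra1a, an adrenergic receptor, by -4.30 (SE 1.27, well above background in 3 of 4 RORasg/sg hearts) and Nr3c2, the mineralocorticoid receptor, by -2.55 (SE 0.764). With the mean of all its probes, Nppa turned to 0.012, and on probes well above background on all arrays Adra1a turned to 0.72. Within slides 1 and 2 the median was -0.21 (adjusted p = 0.338) and -0.28 (adjusted p = 0.0327). The call was lost without WT 4 (0.0809), RORasg/sg 1 (0.0851), RORasg/sg 3 (0.0560) or RORasg/sg 4 (0.0599). Over the 5 brighter arrays its median was -0.38 (adjusted p = 0.40, direction downward). Its adjusted p lay between 0.00282 and 0.40 over 31 alternatives, with 0.0543 under brightness as a covariate.

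Circadian clock genes shifted downward (median -0.40, camera adjusted p = 0.0376, and adjusted p = 0.321 with an estimated correlation), and 10 of its 22 measured members had higher and 12 lower mean signal in RORasg/sg hearts. By limma, 2 members passed adjusted over the list alone, and 0 over all genes, with 1 higher and 7 lower at an unadjusted p under 0.05. Nr1d1 was among those 2 and Dbp was not. Nr1d1, the clock repressor REV-ERBalpha, differed by -2.34 (SE 0.602), and Dbp, a clock output factor, by -1.51 (SE 0.484). The 1 higher member at that p was Per2, a core clock gene outside the naming rule, at 1.70 (-0.17 in the 5 brighter arrays), with -1.99 on its other probe. Known ROR response element targets were not called (median 0.38, camera adjusted p = 0.810), with Avpr1a at -3.48 (SE 1.1, and 0.026 in the 5 brighter arrays), well above background in 1 of the 4 RORasg/sg hearts, Nfkbia at -2.0 and E2f1 at 1.14. Their median and mean (0.0047) were above 0 while camera's direction was downward. Within slides 1 and 2 the median of the clock list was 0.011 (adjusted p = 0.748) and -1.03 (adjusted p = 0.0112), and the call on the clock list was lost without WT 4 (0.0591), RORasg/sg 1 (0.0708), RORasg/sg 3 (0.0910) or RORasg/sg 4 (0.0551). Over the 5 brighter arrays its median was -0.37 (adjusted p = 0.585, direction downward). Over 31 alternatives its adjusted p ran from 0.00378 to 0.748, with 0.0900 under brightness as a covariate.

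Immediate early genes, which respond within minutes to stimuli, shifted downward (median -0.031, camera adjusted p = 0.0220, and adjusted p = 0.321 with an estimated correlation), and 11 of its 23 measured members had higher and 12 lower mean signal in RORasg/sg hearts. Fos differed by -1.81, though well above background in 2 of the 4 RORasg/sg hearts, and Klf4 by -1.74 (SE 0.465), each lower in every RORasg/sg heart than in every WT heart, and Ier2 by -2.67 and Ccn1 by -2.42. By limma, 2 members passed adjusted over the list alone, and 0 over all genes, with 2 higher and 8 lower at an unadjusted p under 0.05. Within slides 1 and 2 the median was -0.17 (adjusted p = 0.676) and -0.24 (adjusted p = 0.0132), and the call was lost without WT 4 (0.0591) or RORasg/sg 1 (0.0552). Over the 5 brighter arrays its median was -0.34 (adjusted p = 0.389, direction downward). Its adjusted p lay between 0.00262 and 0.676 over 31 alternatives, with 0.00670 under brightness as a covariate.

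Endothelial markers shifted downward by camera (adjusted p = 0.0376, and adjusted p = 0.321 with an estimated correlation), with a mean of -0.55 but a median of 0.029, and 11 of its 22 measured members had higher and 11 lower mean signal in RORasg/sg hearts. Flt1, a VEGF receptor, differed by -2.25 (SE 0.596), Erg, an endothelial transcription factor, by -2.03 (SE 0.652) and Tek by -2.67 (SE 1.02, and 0.42 in the 5 brighter arrays, well above background in 3 of 4 RORasg/sg hearts), against Emcn at 1.21 (SE 0.471, and -0.051 in the 5 brighter arrays). By limma, 0 members passed adjusted over the list alone, with 2 higher and 6 lower at an unadjusted p under 0.05. In the 5 brighter arrays the direction turned upward (median 0.27, camera adjusted p = 5.65e-04). Within slides 1 and 2 the median was 0.0050 (adjusted p = 0.889) and -0.37 (adjusted p = 0.00172), with camera's direction upward in slide 1, and the call was lost without WT 4 (0.0868), RORasg/sg 2 (0.0625), RORasg/sg 3 (0.141) or RORasg/sg 4 (0.0599). Over 31 alternatives its adjusted p ran from 5.65e-04 to 0.889, with 0.764 under brightness as a covariate.

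**Figure D3:**
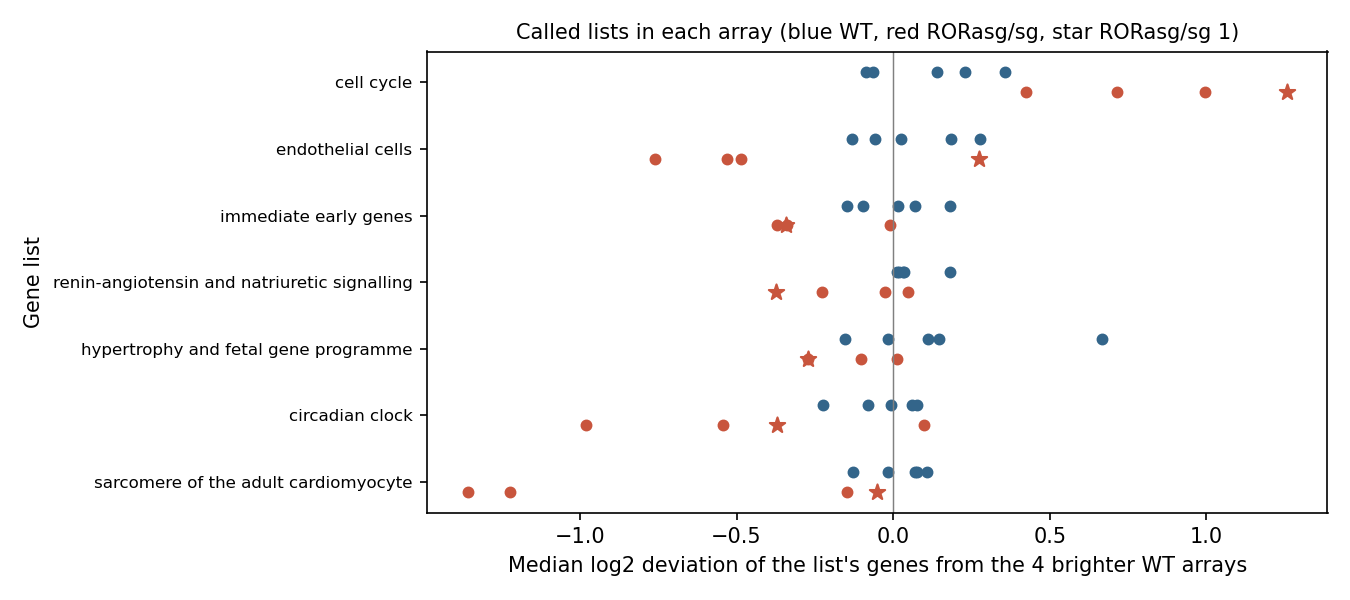
Each point is the median log2 deviation of a called list's genes in 1 array from the mean of the 4 brighter WT arrays (blue WT, red RORasg/sg, star RORasg/sg 1). Cell cycle values of all RORasg/sg arrays lie above those of the WT arrays, while the sarcomere and endothelial values of RORasg/sg 1 lie among the WT arrays. The values are not set against the shift of all genes in each array.

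The other lists were not called by camera. Extracellular matrix genes had a median of 0.29 (camera adjusted p = 0.810, 20 members higher and 10 lower), against 0.46 in the 5 brighter arrays (called upward, adjusted p = 6.56e-06), with Mmp3, a matrix metalloproteinase, at -2.66, Col3a1, a fibrillar collagen chain, at 1.51, Tnc at 2.45 (-0.044 in the brighter) and Col1a1 at 1.67. Cardiac fibroblast markers had a median of 0.66 (camera adjusted p = 0.261, 15 members higher and 6 lower), against 0.29 in the 5 brighter arrays (called upward, adjusted p = 8.20e-04), with Serpinf1, a secreted serpin, at 1.59, Col3a1, a fibrillar collagen chain, at 1.51, Thy1 at 2.10 and Col1a1 at 1.67. The other probes of Col1a1 differed by 1.41 and 0.0023. Smooth muscle and pericyte markers had a median of -0.10 (camera adjusted p = 0.0669, 8 members higher and 10 lower), against 0.092 in the 5 brighter arrays, with Cspg4, a pericyte marker, at 2.0 (-0.87 in the brighter), Vtn at -1.91 (0.65 in the brighter), Myh11 at -1.22 and Acta2 at -1.28 (0.33 in the brighter). Atrial cardiomyocyte markers had a median of 0.55 (camera adjusted p = 0.937, 10 members higher and 5 lower), against 0.043 in the 5 brighter arrays, with Myl7, an atrial myosin light chain, at 1.60, Stard10 at -1.59, Fgf12 at 1.65 and Nppa at -1.20. Calcium handling and ion channel genes had a median of 0.28 (camera adjusted p = 0.261, 15 members higher and 10 lower), against 0.037 in the 5 brighter arrays, with Pln at -1.46, Itpr2, an intracellular calcium channel, at -2.19, Kcnj3 at -1.70 (0.043 in the brighter) and Cacnb2 at -1.71 (0.11 in the brighter).

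Genes of fatty acid uptake and oxidation had a median of 0.048 (camera adjusted p = 0.104, 20 members higher and 19 lower), against -0.41 in the 5 brighter arrays, with Cd36, a fatty acid transporter, at -0.96, Ppargc1b, a coactivator of mitochondrial genes, at -1.66 (0.39 in the brighter), Lpl at 0.94 (-0.60 in the brighter) and Ucp2 at -2.65 (2.12 in the brighter, well above background in 3 of 4 RORasg/sg hearts). Genes of oxidative phosphorylation and the citrate cycle had a median of 0.15 (camera adjusted p = 0.101, 26 members higher and 20 lower), against -0.31 in the 5 brighter arrays and -0.20 in the 4 dimmer arrays (called downward, adjusted p = 0.00844), with Sdhb, a succinate dehydrogenase subunit, at -2.05 (0.14 in the brighter), Ogdh, a citrate cycle dehydrogenase, at -1.48, Dlst at -1.73 and Idh2 at -3.60 (1.09 in the brighter, well above background in 3 of 4 RORasg/sg hearts). Glucose uptake and glycolysis genes had a median of 0.34 (camera adjusted p = 0.462, 17 members higher and 11 lower), against -0.32 in the 5 brighter arrays, with Tpi1, a glycolytic enzyme, at -1.82, Pygm, the muscle glycogen phosphorylase, at -3.54 (1.03 in the brighter), Gys1 at -1.75 (1.19 in the brighter, well above background in 1 of 4 RORasg/sg hearts) and Pfkfb2 at -1.19. Genes of cholesterol and fatty acid synthesis had a median of -0.017 (camera adjusted p = 0.0875, 14 members higher and 14 lower), against -0.15 in the 5 brighter arrays, with Srebf1, a regulator of lipid synthesis, at -3.19 (well above background in 3 of 4 RORasg/sg hearts), Nr1h3, the liver X receptor alpha, at -1.52, Fdft1 at -1.72 and Me1 at -1.21. Mitochondrial dynamics and autophagy genes had a median of 0.11 (camera adjusted p = 0.165, 16 members higher and 12 lower), against -0.29 in the 5 brighter arrays and -0.094 in the 4 dimmer arrays (called downward, adjusted p = 0.0352), with Becn1, an autophagy gene, at -3.52 (0.68 in the brighter, well above background in 1 of 4 RORasg/sg hearts), Tfam, a mitochondrial transcription factor, at -2.52 (0.31 in the brighter), Sirt3 at 1.12 (-0.28 in the brighter) and Mfn2 at -0.48. Antioxidant genes had a median of -0.075 (camera adjusted p = 0.109, 12 members higher and 13 lower), against -0.32 in the 5 brighter arrays, with Gclc, an enzyme of glutathione synthesis, at -2.57 (well above background in 3 of 4 RORasg/sg hearts), Gsta4, a glutathione transferase, at 0.92, Nqo1 at -1.32 and Prdx3 at -0.80. Unfolded protein response and heat shock genes had a median of -0.30 (camera adjusted p = 0.0503, 11 members higher and 14 lower), against -0.25 in the 5 brighter arrays, with Atf4, a stress transcription factor, at -1.66, Hspa5, an endoplasmic reticulum chaperone, at -1.74, Hspa8 at -1.05 and Ddit3 at 0.81.

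Inflammatory cytokine and NF-kB genes had a median of 0.32 (camera adjusted p = 0.810, 21 members higher and 11 lower), against -0.30 in the 5 brighter arrays, with Ccl7, a monocyte chemokine, at -2.25, Nfkbia, an inhibitor of NF-kB, at -2.0, Stat3 at -1.61 (1.23 in the brighter) and Il6st at -3.21 (0.39 in the brighter, well above background in 3 of 4 RORasg/sg hearts). Interferon-stimulated genes had a median of 0.37 (camera adjusted p = 0.532, 15 members higher and 7 lower), against 0.13 in the 5 brighter arrays (called upward, adjusted p = 0.00367), with Ifi44 at 1.83, Ifit3 at 1.71, Rsad2 at -1.74 (0.44 in the brighter) and Isg15 at 0.99. Macrophage and monocyte markers had a median of -0.055 (camera adjusted p = 0.261, 13 members higher and 14 lower), against 0.14 in the 5 brighter arrays (called upward, adjusted p = 5.03e-04), with H2-Aa, an MHC class II chain, at -4.48 (well above background in 2 of 4 RORasg/sg hearts), Cd74, the class II invariant chain, at -3.03, C1qc at 1.60 and Lyve1 at 1.97 (-0.12 in the brighter). Lymphocyte and neutrophil markers had a median of 0.39 (camera adjusted p = 0.810, 13 members higher and 8 lower), against -0.50 in the 5 brighter arrays, with Cd3d, a chain of the T cell receptor complex, at 2.47, Camp, a neutrophil antimicrobial peptide gene, at 0.99 (-0.23 in the brighter) and Cd79a at 0.79 (-0.22 in the brighter). Glucocorticoid-responsive genes had a median of 0.28 (camera adjusted p = 0.810, 12 members higher and 8 lower), against -0.064 in the 5 brighter arrays, with Map3k6 at -1.36 (0.76 in the brighter), Hif3a at 0.95 (-0.38 in the brighter), Fkbp5 at 0.67 (-0.31 in the brighter) and Angptl4 at 0.98 (-1.25 in the brighter). Adipocyte markers had a median of 0.23 (camera adjusted p = 0.898, 14 members higher and 4 lower), against -0.30 in the 5 brighter arrays, with Cebpa, an adipocyte transcription factor, at 0.93, Acvr1c at 0.97 (-0.37 in the brighter), Thrsp at 0.78 and Plin4 at -0.75 (0.23 in the brighter). Red blood cell genes had a median of 0.070 (camera adjusted p = 0.109, 6 members higher and 6 lower), against -0.080 in the 5 brighter arrays and -0.88 in the 4 dimmer arrays (called downward, adjusted p = 0.0335), with Alas2, an enzyme of haem synthesis in red cells, at -4.42 (0.22 in the brighter, well above background in 3 of 4 RORasg/sg hearts), Bpgm at -2.43 (0.39 in the brighter) and Tfrc at -1.59 (1.38 in the brighter). Neuron, Schwann cell and mesothelial markers had a median of 0.63 (camera adjusted p = 0.164, 15 members higher and 3 lower), against -0.35 in the 5 brighter arrays, with Msln, a mesothelial marker, at 1.92, Sox10, a Schwann cell transcription factor, at 2.59 (-0.40 in the brighter) and Upk3b at 1.03 (-0.16 in the brighter). Markers of skeletal muscle, lung, liver and thymus had a median of -0.00021 (camera adjusted p = 0.532, 9 members higher and 10 lower), against -0.28 in the 5 brighter arrays, with Acta1, skeletal actin, at -2.59, Tnni2, a fast skeletal troponin, at -1.79 (0.21 in the brighter), Scgb1a1 at 1.15 and Myh1 at 1.58.

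The other probe of H2-Aa differed by -0.21. Adjusted over the list alone, limma called 2 members each of the extracellular matrix, fibroblast, macrophage and red cell lists and 1 of the inflammatory list, and 0 of each other list in this group. Against that 0, the most members at an unadjusted p under 0.05 were 6 lower in oxidative phosphorylation and 4 higher in interferon-stimulated genes. Median and mean differed in sign in calcium handling, glycolysis, oxidative phosphorylation, fatty acid oxidation, mitochondrial dynamics and red cells, where the median was above 0 and camera's direction downward. In the inflammatory, glucocorticoid and atrial lists both median and mean were above 0 and camera's direction downward.

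Genes near Rora on chromosome 9 were compared with all other genes, since a mutation bred into a strain can carry linked sequence with it. Within 20 Mb of Rora, Rora left out, 1 of 322 genes passed the threshold, AI593442, against 0 of 17582 elsewhere (Fisher's exact test, two-sided, p = 0.0180). With windows of 10 and 5 Mb, which do not reach AI593442, the p was 1. The comparison rests on that gene alone.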

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

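The tests of the dimmer arrays were chosen after the arrays' values had been seen, and the counts over other splits of the arrays were planned. Of 50 checks of a group for an array far from the others, 6 stood out, and chance gives about 1 in 20. WT 4 was the lowest WT array for Rora (1.51, next 2.87) and for Slc22a3 (-4.45, next -2.86), and the highest for the median of the renin-angiotensin list (0.18, next 0.034). List medians are deviations from the mean of the brighter WT arrays, which centres those arrays near 0. Among WT arrays, WT 4 thus stands out more easily in list medians, and the 1 in 20 does not hold for them. WT 5 was lowest for 2210407C18Rik (-3.56, next -2.96). RORasg/sg 1 was highest of its group for Mblac2 (-1.78, next -6.80), and RORasg/sg 2 for the median of the immediate early list (-0.0088, next -0.34).

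WT 4 and RORasg/sg 2, 3 and 4 deviated from the brighter WT arrays together. Across genes, which are not independent replicates, the deviation of WT 4 correlated with the mean of those RORasg/sg arrays at r = 0.563 with disjoint controls. The brighter WT arrays gave r from -0.328 to 0.151, and RORasg/sg 1 gave r = -0.306, within that range. RORasg/sg 1, a single heart, thus did not share the deviation of RORasg/sg 2, 3 and 4, which argues against genotype as the whole cause. Different probes of a gene disagreed at least 3.13 times as much in the dimmer arrays as in any brighter WT array and 1.48 times as much in RORasg/sg 1, over 6335 genes, so uneven amplification or RNA quality in single libraries may account for part of it. No RNA quality value was used here, and how much of the deviation of RORasg/sg 2, 3 and 4 is genotype stays open, since 3 of the 4 dimmer arrays are RORasg/sg. A biological difference between these hearts was not tested beyond genotype.

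Among 100 of the 126 splits of the arrays into 5 and 4, the real one included, 4 gave as many genes past the threshold as the real split, which gave 1, and 4 as many also changed 2-fold. That share lies just under 0.05, the level below which chance was to be called excluded. Not all 126 splits were run, and the count fell to 0 when any of 7 of the 9 arrays was left out. Chance is thus only weakly argued against for a count of 1. The other splits that matched it called 13379 (12368 at 2-fold), 5044 and 1 genes, and the highest set WT 4 and RORasg/sg 2, 3 and 4 against the rest, which points to a structure of the samples along brightness. With brightness as a covariate the real comparison called 1 gene. Counts within the 4 dimmer or the 5 brighter arrays rest on the spread assumed for a lone heart. For the 7 lists called, 23 of 100 splits gave as many, the real one included, and the highest other 17, so chance is not excluded for that count.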

How the results depend on the processing

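The settings on the brighter arrays, the dimmer arrays and brightness as a covariate were chosen after the data were seen, as was the median spot signal in normexp. Against 1 gene in the main setting, 0 passed with normexp with the 75th percentile, a filter on all 9 arrays, the mean of all probes, slide as a block, slide as a block without slide 3, slide 1 alone, slide 2 alone or in the 4 dimmer arrays, and 0 were also changed 2-fold there. Quantile normalization gave 2 (2 at 2-fold), the unscaled deposited values 3 (3), array weights 15135 (13498 at 2-fold; 10504 higher, 4631 lower) and the 5 brighter arrays 1189 (903 at 2-fold). Leaving out single arrays gave 0 to 10390 genes and 0 to 9578 at 2-fold, the highest without RORasg/sg 1. Array weights gave RORasg/sg 1 the lowest weight, 0.101, against 0.332, 1.69 and 0.526 for RORasg/sg 2, 3 and 4. That setting comes near to leaving RORasg/sg 1 out, so its count is not separate from the count without that array. The cause of these changes in count was not tested. The share of probes well above background was 85.5% in WT and 83.6% in RORasg/sg hearts (exact two-sided permutation test, p = 0.270), and whether signal over background limits the changes that can be seen was not tested.

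Replicate numbers did not pair the samples: the correlation of same-numbered arrays' deviations was 0.046, -0.0064, -0.33 and 0.39, and WT 4 correlated best with both RORasg/sg 3 and RORasg/sg 4, WT 3 with RORasg/sg 1 and WT 5 with RORasg/sg 2. With the replicate block, 9 genes passed (9 at 2-fold), Rora at -4.05 among them, and Fisher's exact test of genes near Rora gave p = 0.0700. The adipocyte list turned, at 0.21.

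Rora stayed lower in every setting run. It passed with array weights (-4.40) and, on 1 RORasg/sg heart, in the 5 brighter arrays (-2.94), and leaving out single arrays gave -4.63 to -3.70, past the threshold without RORasg/sg 1. In the other settings, the replicate block aside, it stayed short of the threshold. For genes near Rora, p was 0.0530 in the unscaled values, 0.497 with array weights and 0.620 in the 5 brighter arrays and 1 with windows of 10 and 5 Mb. It was 0.0180 to 0.815 where leaving out an array still called a gene, and settings that called 0 genes give no value.

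Against 7 lists called, the number was 13 with quantile normalization, 15 and 12 with normexp and either scaling, 4 unscaled, 12 without a filter, 3 with the filter on all arrays, 3 and 16 within slides 1 and 2, 6 in the 5 brighter arrays (6 upward and 0 downward), 7 in the 4 dimmer (0 upward and 7 downward), 8 with brightness as a covariate (4 upward and 4 downward), 0 with an estimated correlation, 0 by fry, and 1 to 13 when single arrays were left out. The 7 were 1 upward and 6 downward. The balance of directions thus turned in the brighter arrays, where the lone RORasg/sg heart is assumed to vary like the WT hearts, as the lone WT heart of the dimmer arrays is assumed to vary like the RORasg/sg hearts. With the covariate, the sarcomere, hypertrophy, immediate early and cell cycle calls held, and the clock, renin-angiotensin and endothelial calls were lost. Camera then also called the extracellular matrix (adjusted p = 0.0250), fibroblast (0.0499) and interferon-stimulated (0.0405) lists upward and oxidative phosphorylation (0.0153) downward.

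List and gene directions turned as follows, given as the list's median where the direction of its test turned, or the gene's log2 difference, and the cause was not tested. With quantile normalization, these were adipocytes 0.027. With normexp and the 75th percentile, these were adipocytes 0.20 and Gys1 0.015. With normexp and quantile normalization, these were atrial cardiomyocytes 0.24 and adipocytes -0.011. In the unscaled values, these were adipocytes -0.34. Without a filter, these were adipocytes 0.23. With the filter on all arrays, these were adipocytes 0.23 and Adra1a 0.72. With the mean of all probes, these were extracellular matrix and fibrosis 0.21, atrial cardiomyocytes 0.57, Nppa 0.012 and Acta2 0.13. With slide as a block, with or without slide 3, these were atrial cardiomyocytes 0.58 and adipocytes 0.21. Within slide 1, these were sarcomere of the adult cardiomyocyte 0.099, calcium handling and ion channels 0.23, fatty acid uptake and oxidation 0.11, oxidative phosphorylation 0.35, glucose uptake and glycolysis 0.35, mitochondrial dynamics 0.32, antioxidant and NRF2 targets 0.26, inflammatory cytokines 0.065, glucocorticoid-responsive genes 0.29, cholesterol and fatty acid synthesis 0.031, unfolded protein response and heat shock 0.17, macrophages and monocytes 0.24, endothelial cells 0.0050, smooth muscle cells and pericytes 0.14, atrial cardiomyocytes 0.10, adipocytes -0.090, Idh2 0.14, Angptl4 -0.52, Vtn 0.10, Acta2 0.17 and Plin4 0.17. Within slide 2, these were extracellular matrix and fibrosis 0.085, interferon-stimulated genes 0.37 and lymphocytes and neutrophils 0.38. With array weights, these were extracellular matrix and fibrosis 0.24, known ROR response element targets 0.67 and adipocytes 0.14. By fry, these were known ROR response element targets 0.38, glucose uptake and glycolysis 0.34, inflammatory cytokines 0.32, glucocorticoid-responsive genes 0.28, atrial cardiomyocytes 0.55 and other tissues -0.00021. In the 4 dimmer arrays, these were extracellular matrix and fibrosis 0.45. With brightness as a covariate, these were calcium handling and ion channels 0.097, glucocorticoid-responsive genes 0.069, macrophages and monocytes 0.20, lymphocytes and neutrophils -0.052, atrial cardiomyocytes 0.097, Angptl4 -0.0043 and Tfrc 0.34. In the 5 brighter arrays, these were sarcomere of the adult cardiomyocyte -0.051, calcium handling and ion channels 0.037, oxidative phosphorylation -0.31, glucose uptake and glycolysis -0.32, mitochondrial dynamics -0.29, antioxidant and NRF2 targets -0.32, inflammatory cytokines -0.30, glucocorticoid-responsive genes -0.064, cholesterol and fatty acid synthesis -0.15, unfolded protein response and heat shock -0.25, macrophages and monocytes 0.14, lymphocytes and neutrophils -0.50, endothelial cells 0.27, smooth muscle cells and pericytes 0.092, atrial cardiomyocytes 0.043, red blood cells -0.080, other tissues -0.28, Kcnj3 0.043, Cacnb2 0.11, Tnc -0.044, Avpr1a 0.026, Ppargc1b 0.39, Lpl -0.60, Ucp2 2.12, Sdhb 0.14, Idh2 1.09, Pygm 1.03, Gys1 1.19, Becn1 0.68, Tfam 0.31, Sirt3 -0.28, Stat3 1.23, Il6st 0.39, Rsad2 0.44, Map3k6 0.76, Hif3a -0.38, Fkbp5 -0.31, Angptl4 -1.25, Lyve1 -0.12, Camp -0.23, Cd79a -0.22, Tek 0.42, Emcn -0.051, Cspg4 -0.87, Vtn 0.65, Acta2 0.33, Acvr1c -0.37, Plin4 0.23, Alas2 0.22, Bpgm 0.39, Tfrc 1.38, Sox10 -0.40, Upk3b -0.16, Tnni2 0.21 and Ccnd2 0.88. When single arrays were left out, directions turned in some of the 9 fits, and the ranges of medians given here run over all 9. Atrial cardiomyocytes turned in 4 fits (0.27 to 0.59). Inflammatory cytokines (0.24 to 0.57) and glucocorticoid-responsive genes (-0.039 to 0.34) turned in 2 each. Adipocytes (0.12 to 0.48), extracellular matrix and fibrosis (0.22 to 0.53) and known ROR response element targets (0.13 to 0.74) turned in 1 each. So did interferon-stimulated genes (0.28 to 0.61) and lymphocytes and neutrophils (0.10 to 0.67). Over all settings, single genes kept direction and side of the threshold in 3047 cases and lists in 689. With the direction kept, genes passed anew in 234 cases and lists in 67, and a call was lost in 15 cases for genes and 65 for lists. The direction turned in 49 cases for genes and 78 for lists, and calls gained or lost with a turn are not in those counts. Of the 7 called lists, the sarcomere and endothelial lists turned, both within slide 1 and in the 5 brighter arrays.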

Other observations

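All the tests in this part were chosen after the values had been seen. Of 9 measured genes of MHC class II antigen presentation, 4 were lower in every RORasg/sg heart than in every WT heart, and 0 passed the threshold in limma, with an adjusted p of 0.340 or above; the group, which ran from -4.48 to 1.37, was not tested against all genes. The log2 difference was -4.48 (SE 0.859; -1.26 in the brighter arrays) for H2-Aa, -3.03 (SE 0.589; -1.72 in the brighter arrays) for Cd74, the invariant chain, -3.54 (SE 0.701; -1.09 in the brighter arrays) for H2-DMb1 and -1.21 (SE 0.432; -1.04 in the brighter arrays) for H2-Ab1, with H2-Aa well above background in 2 of the 4 RORasg/sg hearts. H2-DMa, at 1.37, and Ciita, the class II transactivator, at 0.44, lay on the other side over all arrays, but at -0.77 and -0.68 in the brighter arrays, which hold a single RORasg/sg heart. The other probes of H2-Aa (-0.21) and H2-DMb1 (0.71) differed from those used, and those of H2-Ab1 stood at -2.73 and, in the opposite direction, 0.96.

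Fewer macrophages would lower their other markers too. The class II set of 9 genes had a median of -0.34 and 21 other macrophage markers 0.13, a gap of -0.47 (permutation over genes, two-sided, p = 0.306). Both medians lay below that of all genes (0.41). The gap is within the limit written down for fewer macrophages. That limit was set aside because class II members lie on both sides of 0, a condition added after the value was seen, so the test decides nothing. In RORasg/sg 1 the class II median was -0.77, between the values that would speak for and against the dimmer arrays as the source. A loss of macrophages and the dimmer arrays both stay open, as does an effect of genotype on class II genes themselves, which was not tested.

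Among genes with an unadjusted p under 0.001, 4 of 322 within 20 Mb of Rora stood against 37 of 17582 elsewhere (Fisher's exact test, two-sided, p = 0.00616, odds ratio 5.96), and they were AI593442, Arhgap20os (-2.54), Plet1os (-3.68) and Aldh1a2 (2.74), named after their values were seen. Sequence of another strain carried along with the mutation may be behind this. Of 11150 windows of 322 genes elsewhere, 0 held as many, and the highest held 3 against 4. Those windows were drawn from 17582 genes and overlap, so they are not separate tests and their share is no p-value. With windows of 10 and 5 Mb, Fisher's exact test, two-sided, gave p = 0.308 and 0.183 (odds ratios 2.78 and 5.11). With brightness as a covariate, Fisher's exact test, two-sided, gave p = 0.0541 (odds ratio 5.78). In the 5 brighter arrays, which hold 1 RORasg/sg heart, the odds ratio was 1.37. The requirement that the excess also hold in those settings was set after their values were known, and the explanation stays open. A sequence variant under a single probe is argued against for AI593442, since 3 of its 3 probes were lower in every RORasg/sg heart. An effect of RORalpha on these genes was not tested apart from their position.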
